A study of Mus musculus with 8 samples.

How the data were processed

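Ventricles of C57BL/6 mice at postnatal day 21 were frozen, total RNA was extracted and poly(A) RNA was made into strand-specific libraries, per the labels' protocols. The submitters' design text names 4 samples per group, from cardiac Med1 knockout mice and from mice with floxed Med1, called WT here. It says neither which promoter drove the deletion nor whether each sample was 1 animal. If it was not, p-values measure only the spread between these samples. Reads were aligned to mm10 with the TopHat application (version 1.0.0), and transcripts were assembled and compared with Cufflinks and Cuffdiff, per the submitters' processing notes and design text. The versions of Cufflinks and Cuffdiff, the gene annotation, the read length and whether counting used strand are not given in the sources used here.

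The authors deposited FPKM per gene and library, per the file headers, in a table of 23847 rows. In every library 312 rows hold a word for too little data in place of a number, and 1 further estimate failed for Cacna2d1 in WT 2. The authors wrote 0.001 FPKM where the estimate was 0, and this was set back to 0. A symbol occurred more than once in 523 rows, which were kept apart by position, with the most abundant row standing for its symbol in lists. A spreadsheet had turned 27 symbols into dates. The second deposited table holds the authors' pooled FPKM per group, log2 fold changes, p-values and q-values for 23352 genes. Its fold changes were lost to a spreadsheet error in 531 rows, and directions there come from the pooled FPKM. Its smallest p-value is 5e-05. FPKM divides by transcript length and by the fragments of the library, so that a gene's value falls when others take more of the total, and reads shared by near-identical genes are split by the software.

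Library names in the table matched the labels' descriptions, and groups and replicate numbers come from the titles. Fragment counts were not recoverable from FPKM, but genes under 0.05 FPKM in a pair of libraries gave sharp steps of whole fragments, whose ratio is the relative depth of the pair. The ratio to knockout 1 was 1.03, 1.04 and 1.1 for the other knockout libraries and 0.97, 1.05, 1.09 and 1 for the WT libraries.

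The main test was limma (version 3.58.1 in R 4.3.3) on log2(FPKM + 1), with an intensity trend, for genes with a mean of at least 1 FPKM over all 8 libraries. Benjamini-Hochberg adjusted p-values under 0.05 were called, and all tests were two-sided. Log2 changes are knockout minus WT on that scale, and standard errors are limma's. Med1 was also compared by an exact permutation test. Gene lists of cardiac function, metabolism, stress and cell types, 44 in all, were fixed before the data were examined, as were the test and the rule for named genes. Lists with at least 5 members past the minimum, other than the sex-linked check genes, were tested with camera at a preset correlation of 0.01, with camera at a correlation estimated per list, and with fry, each adjusted over the lists tested. The rule named Med1, the 12 largest rises and 12 largest falls among called genes whose libraries did not overlap between groups, up to 4 called members per list (or the 2 most abundant where none passed) and a fixed set of heart and sex-linked genes. Predicted genes, microRNA and small nucleolar RNA genes and joined loci were left out of the largest changes. Other members named in the text were chosen after their values were seen.

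The same procedure was tested on simulated data for this comparison, with 11974 genes and known changes. It recovered 50.8% of genes changed by 0.5 on the log2 scale, 92.2% of those changed by 1 and 100% of those changed by 2, and 3.68% of the calls were unchanged genes. Only 65, 64 and 65 genes past the minimum had these changes, and no common shift was simulated. The real comparison called 7336 genes with a median shift of 0.25, so these rates need not hold for it. Alternatives were a pseudocount of 0.1, no expression minimum or one of 5 FPKM, median-of-ratios rescaling, quantile normalization, limma without trend, with robust variances or with array weights, the replicate number as a block, and each library left out in turn, besides 2 settings with several libraries left out that were added after the data were seen. Loci in the table count from 0 and are printed from 1.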

Results

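Poly(A)-selected RNA from mouse heart ventricles at postnatal day 21 was measured in 8 libraries. Of these, 4 came from mice lacking Med1 in the heart and 4 from mice with a floxed, intact Med1 (WT). Med1 is a subunit of Mediator, the complex that links transcription factors, nuclear receptors among them, to RNA polymerase II. The comparison asks which ventricular transcripts depend on Med1 at this age. Values were FPKM (fragments per kilobase of transcript, scaled to the fragments of the library), whose totals ran from 481719 to 502629 in the knockout libraries and from 507484 to 536174 in WT. Between 11526 and 12273 genes reached 1 FPKM per library. The total number of fragments per library is unknown. The value of 1 fragment could be read from genes near the bottom of the range, and by it the libraries had 0.97 to 1.1 times the relative depth of knockout 1.

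Med1 was lower in every knockout library. The 4 knockout libraries had 7.80, 8.37, 7.89 and 9.15 FPKM and the 4 WT libraries 15.5, 16.1, 10.6 and 16.8. The means were 8.31 ± 0.619 and 14.8 ± 2.83 FPKM (SD, n = 4 each), so that the knockout mean was 56.3% of WT. The exact two-sided permutation p was 0.0286, the smallest that 70 assignments of 4 against 4 can give. In limma the log2 change was -0.74 (adjusted p = 0.0011). The gene lies on chromosome 11 from 98152155 to 98193293 (mm10) and is protein-coding. The deposited values are totals per gene, so the floxed exons were not looked at separately.

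**Figure D1:**
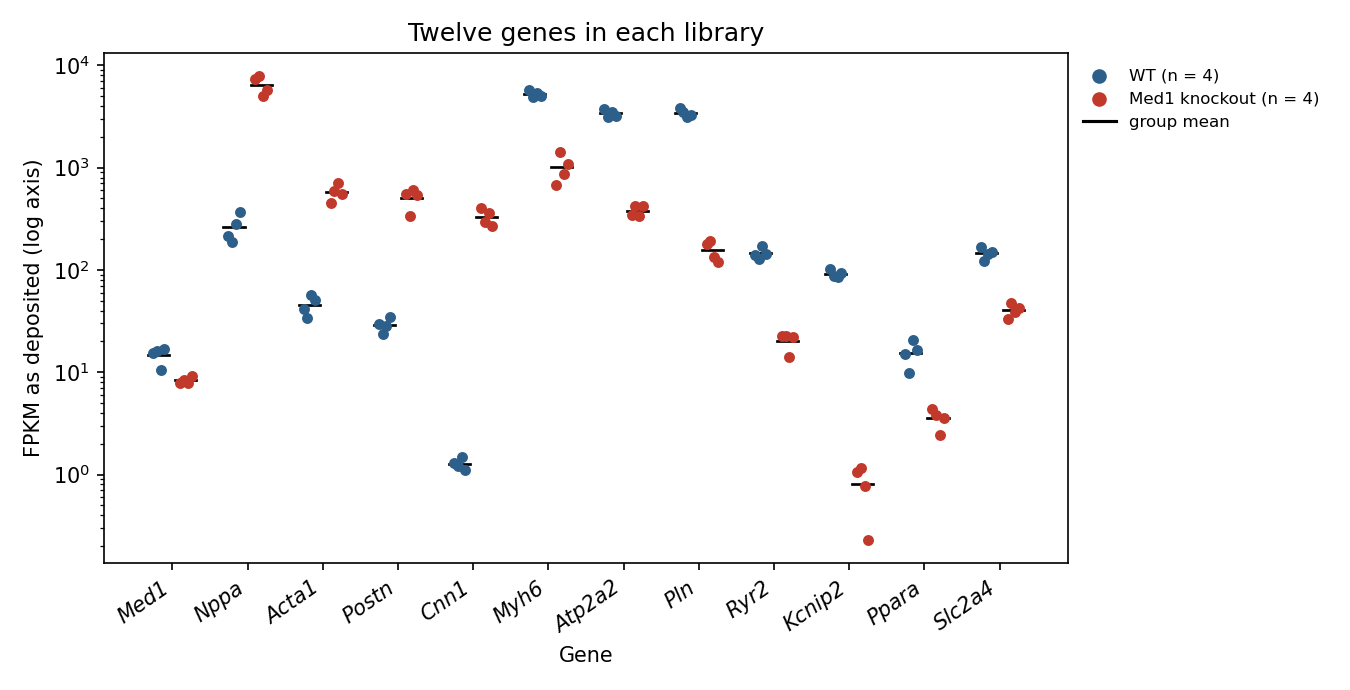
FPKM on a log axis for 12 genes in each of the 8 libraries, blue for WT and red for knockout, with a black line at each group mean. The 4 knockout libraries lie on 1 side of the 4 WT libraries for each gene, from 331 against 1.28 FPKM for Cnn1 to 0.8 against 92.0 FPKM for Kcnip2 (group means).

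The ventricular transcriptome differed widely between the groups. Among 11975 genes with a mean of at least 1 FPKM, 5372 were higher and 1964 lower in the knockout at an adjusted p under 0.05. A fold of 2 or more was reached by 1081 of the higher and 618 of the lower genes. The 4 knockout libraries lay wholly above or below the 4 WT libraries in 57.1% of the genes tested, where chance gives 2.86%. This share was counted on FPKM as deposited, so a common shift between the groups can add to it. It was not counted after rescaling. The median of all genes was itself 0.25 higher in the knockout on the log2 scale. With the libraries rescaled to a common median, 3225 genes were higher and 3235 lower, and the median change was 0. Quantile normalization gave 3437 and 3066. The higher share of calls was thus 73.2% as deposited, 49.9% rescaled and 52.9% quantile normalized. Changes of list members are given as deposited, and the rescaled counts follow where they matter. The first principal component held 70.3% of the variance and separated the groups.

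**Figure D2:**
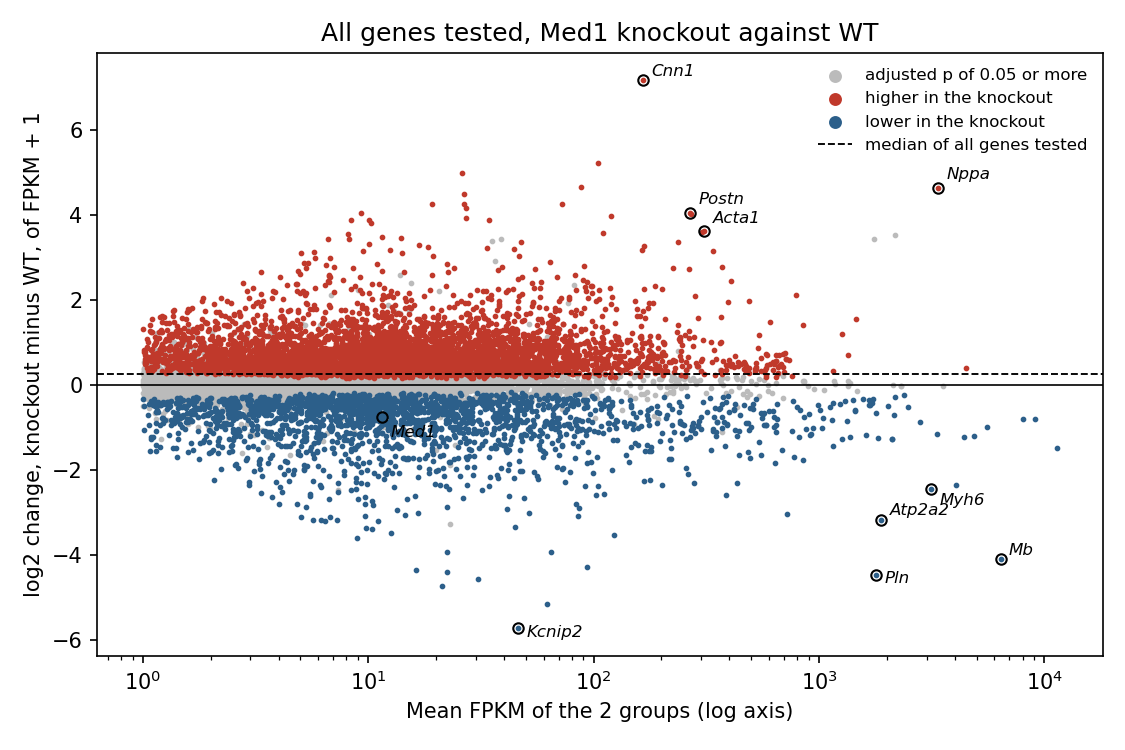
Log2 change (knockout minus WT, of FPKM + 1) against mean FPKM on a log axis for the 11975 genes tested, 1 point per gene, red higher and blue lower at an adjusted p under 0.05, grey not passing. The dashed line marks the median change of 0.25, and the circled genes reach from 7.17 for Cnn1 to -5.72 for Kcnip2.

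The largest fall was in Kcnip2. This gene, the accessory subunit of the fast transient outward potassium current (chromosome 19, 45792346 to 45816063), fell from 92.0 ± 7.45 to 0.8 ± 0.413 FPKM (SD, n = 4). Its log2 change was -5.72 ± 0.165 (SE, limma adjusted p = 1.25e-07). Pln, which encodes the calcium pump regulator phospholamban (chromosome 10, 53337686 to 53345999), fell from 3420 ± 309 to 156 ± 35.7 FPKM. Mb, the oxygen store myoglobin, fell from 12100 ± 483 to 715 ± 132 FPKM. Art1, Mylk4, Lrtm1, Asb14, Ogdhl, Fndc5 and Lrrc15 fell by 35.2, 26.3, 23.5, 21.1, 20.4, 15.1 and 12.1 times. Rpl3l, a ribosomal protein made in striated muscle, fell 19.6 times. Ces1d fell 15.2 times, with knockout 4 at 7.77 FPKM and the other knockout libraries at 0.747 to 0.904.

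The largest rise was in Cnn1, which encodes the smooth muscle protein calponin 1 (chromosome 9, 22099253 to 22109221). It rose from 1.28 ± 0.157 to 331 ± 62.0 FPKM (SD, n = 4), a log2 change of 7.17 ± 0.129 (SE, limma adjusted p = 6.61e-09). Tpm2, a tropomyosin, rose 25.2 times and Rnd1 31.6 times. Wisp2 rose 22.4 times, and the matrix genes Col8a1, Lox, Cilp and Postn rose 19.1, 19.1, 17.8 and 16.6 times. Nppa, the atrial natriuretic peptide (chromosome 4, 148000746 to 148002067), rose from 263 ± 82.0 to 6480 ± 1310 FPKM, or about 25 times. The other genes among the 12 largest rises, Myl7, Myl4 and Sln, are atrial and varied strongly between knockout libraries. Folds are on the scale of FPKM + 1, which understates those of low genes.

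Genes of cardiac stress and the fetal heart rose as a group, except Myh7. Of 15 members measured, 13 rose, 1 fell and 1 did not pass. The skeletal actin Acta1 rose from 45.7 ± 9.99 to 573 ± 107 FPKM (SD, n = 4), and Nppb, the brain natriuretic peptide, from 130 ± 47.8 to 681 ± 145 FPKM. Uchl1 and the growth factor gene Ctgf each rose 10.3 times, Gdf15 7.99 times and Ankrd1 3.92 times. Myh7, the slow myosin heavy chain that is abundant in the fetal mouse ventricle, went the other way, from 153 ± 64.2 to 16.8 ± 6.14 FPKM (limma adjusted p = 6.11e-05). The list was called by camera (adjusted p = 0.001) and not with an estimated correlation (adjusted p = 0.22). Adjusted over the list alone, counts equal those over all genes in this and every other list, unless another count is given.

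Most sarcomere genes fell. Of 23 members, 18 fell and 3 rose, and 19 fell and 1 rose after rescaling. The adult myosin heavy chain Myh6 fell from 5280 ± 402 to 1010 ± 321 FPKM (SD, n = 4) and the cardiac troponin I gene Tnni3 from 6790 ± 495 to 1330 ± 206 FPKM. Their log2 changes were -2.44 and -2.36 as deposited and -1.84 and -1.69 after quantile normalization. Myom2 fell 4.77 times and Cmya5 3.60 times. Ttn, the titin gene, had a smaller log2 change of -0.76. Actn2, Pdlim5 and Tnnc1 rose by 0.60, 0.46 and 0.41 on the log2 scale as deposited, and Actn2 alone of these after rescaling (0.32). The camera adjusted p was 3.5e-09, against an adjusted p of 0.23 with an estimated correlation. Myh6 encloses a microRNA gene, and both failed with excess data in the authors' deposited table, so its fold rests on the values per library.

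Calcium handling genes split. Of 21 members, 9 fell and 4 rose (11 and 4 after rescaling). The calcium pump gene Atp2a2 (chromosome 5, 122453513 to 122502225) fell from 3400 ± 270 to 380 ± 44.2 FPKM (SD, n = 4), a log2 change of -3.16 ± 0.103 (SE, limma adjusted p = 2.16e-07). Ryr2, the calcium release channel, fell from 146 ± 18.3 to 20.4 ± 4.22 FPKM. Pln fell as given above. Casq1, the calsequestrin of skeletal muscle, rose from 31.9 ± 10.6 to 163 ± 48.9 FPKM, and Casq2, that of the heart, rose by 0.77 on the log2 scale. The sodium-calcium exchanger gene Slc8a1 had a log2 change of 0.11 and did not pass. The camera adjusted p was 0.0011, and 0.22 was the adjusted p with an estimated correlation.

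Ion channel genes fell without an exception among those called. Of 17 measured members, 14 fell and 3 did not pass, with a median log2 change of -1.72. Besides Kcnip2, the potassium channel gene Kcnd2 fell 9.10 times, the channel subunit gene Kcne1 5.93 times and Gja1, the gap junction protein connexin 43, from 191 ± 17.1 to 31.9 ± 5.73 FPKM (SD, n = 4). Camera gave an adjusted p of 4.2e-12 and, with an estimated correlation, an adjusted p of 0.066. Of 14 thyroid hormone responsive genes, 12 fell and 1 rose. These are Pln, Kcnd2, Atp2a2, Myh7, Ucp3, Kcne1, Myh6, Hcn2, Hcn4, Thrsp, Adrb1 and Klf9 as against Nppa. In textbook accounts thyroid hormone raises Myh6, Atp2a2 and Kcnd2 and lowers Myh7 and Pln, so the members that fell include genes of both kinds. It was the only list whose camera call (adjusted p = 9.4e-08) held with an estimated correlation (adjusted p = 0.043), and many of its members also stand in the lists above.

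Genes of fatty acid use fell broadly. Of 24 fatty acid uptake and oxidation genes, 20 fell and none rose. The thiolase Acaa2 fell from 718 ± 192 to 144 ± 30.9 FPKM (SD, n = 4), and Hadh, Slc27a1 and Etfb fell 3.35, 3.19 and 3.14 times. Cpt1b, the muscle carnitine palmitoyltransferase, fell 1.88 times (limma adjusted p = 0.00163). Of 19 PPAR target genes, 9 fell and none rose. The lipoprotein lipase gene Lpl fell from 997 ± 120 to 278 ± 29.3 FPKM, Ucp3 8.27 times, Plin5 6.06 times and Ech1 3.25 times. Pdk4, a kinase that restrains glucose oxidation, varied from 36.7 to 547 FPKM in WT, and its log2 change of -0.91 did not pass (adjusted p = 0.253). Without WT replicate 4 it was -1.57 (adjusted p = 0.014, from 0.014 to 0.63 over the alternatives). Without WT replicate 2 the change of Ucp3 went from -3.05 to -2.46. The camera adjusted p values were 5.2e-13 and 5.6e-06, against an adjusted p of 0.22 and 0.44 with an estimated correlation.

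Nuclear genes of mitochondrial respiration were lower almost throughout. In the pyruvate dehydrogenase and TCA cycle list 23 of 24 fell (24 adjusted over the list alone). In complex I 30 of 36 fell (32 adjusted over the list alone, 36 after rescaling), in complexes III and IV 19 of 23, and among ATP synthase and adenine nucleotide carrier genes 19 of 20. None rose in these 4 lists. Median log2 changes were -1.02, -0.62, -0.69 and -0.66. Cs, the citrate synthase gene, fell from 756 ± 47.2 to 237 ± 66.0 FPKM (SD, n = 4), and Idh3b, Sdhb and Ogdh fell 2.72, 2.55 and 2.48 times. Ndufb10 fell from 1010 ± 64.8 to 355 ± 70.7 FPKM, and Ndufs7, Ndufs1 and Ndufs8 fell 2.87, 2.42 and 2.33 times. Uqcrc1, Cox7a1, Cox6a2 and Cycs fell 2.99, 2.41, 2.38 and 2.06 times, and Atp5g3, Atp5g1 and Atp5a1 2.41, 2.34 and 2.26 times. Slc25a4, the adenine nucleotide carrier of heart and muscle, fell from 6140 ± 395 to 2650 ± 190 FPKM. After quantile normalization its log2 change was -0.23 and did not pass (adjusted p = 0.091, from 1.6e-06 to 0.091 over the alternatives). Camera gave adjusted p values of 1e-15, 7.7e-17, 1.2e-10 and 2.1e-12, and each list had an adjusted p of 0.22 with an estimated correlation. Among mitochondrial biogenesis and dynamics genes, 12 of 20 fell and 4 rose (15 and 1 after rescaling). The coactivator genes Ppargc1b and Ppargc1a fell 4.27 and 3.14 times and the fusion gene Mfn2 2.01 times (camera adjusted p = 6e-05). With an estimated correlation the adjusted p was 0.22. The 15 mitochondrially encoded genes of a further list are absent from the deposited table. Phb2 fell 1.94 times.

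Breakdown of ketones and branched-chain amino acids followed the same direction, with 17 of 18 genes lower and none higher. Mccc2 fell from 32.6 ± 1.58 to 7.26 ± 0.949 FPKM (SD, n = 4), and Bckdhb, Ppm1k and Pccb fell 3.33, 3.27 and 2.45 times. Camera gave an adjusted p of 4.2e-12, and the adjusted p was 0.096 with an estimated correlation. Glucose uptake and glycolysis genes were divided, with 9 of 22 higher and 10 lower (4 and 12 after rescaling), and camera did not call them (adjusted p = 0.062). The insulin-regulated transporter Slc2a4 fell from 146 ± 18.4 to 40.5 ± 6.10 FPKM and the muscle phosphofructokinase Pfkm from 405 ± 21.5 to 107 ± 28.0 FPKM. Pfkfb1 fell 2.38 times. The broadly expressed transporter Slc2a1 rose 2.35 times, and the platelet-type phosphofructokinase Pfkp rose from 24.4 ± 2.32 to 90.0 ± 12 FPKM. Lipid synthesis and storage genes gave 4 higher and 6 lower of 18 (1 and 6 after rescaling, camera adjusted p = 0.088). Dgat2, Lpin1, Gpam and Acacb fell 5.18, 5.07, 2.50 and 2.18 times. Camera called the glycolysis list, towards lower values, without knockout 2 or WT 2 (adjusted p = 0.037 and 0.048) and the lipid synthesis list without knockout 4 or WT 4 (0.045 and 0.041).

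Among 24 nuclear receptor genes, 9 fell and 5 rose (12 and 2 after rescaling). Rxrg fell from 39.2 ± 2.18 to 6.46 ± 1.72 FPKM (SD, n = 4) and Ppara, which drives fatty acid oxidation genes, from 15.4 ± 4.45 to 3.54 ± 0.824 FPKM. Nr3c2 fell 2.12 times and Esrra 1.96 times, while Nr1h3 rose 2.40 times. The camera adjusted p was 0.012, and 0.22 was the adjusted p with an estimated correlation. Cardiac transcription factors were mostly below the threshold, with 4 of 19 higher and 3 lower (2 lower adjusted over the list alone, 2 higher and 9 lower after rescaling). Tbx20 rose 2.40 times and Srf 1.60 times, and Tbx5 and Irx4 fell 1.87 and 1.77 times (camera adjusted p = 0.3).

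Of the other 31 Mediator subunits measured, 21 rose and 1 fell, which became 11 and 5 after rescaling. Med15 rose from 8.10 ± 0.763 to 18.7 ± 0.923 FPKM (SD, n = 4), and Med21, Med14 and Med30 rose 2.08, 1.96 and 1.96 times. Med16 was the member that fell, by 0.79 on the log2 scale. Camera did not call the list (adjusted p = 0.064). Of 74 cytosolic ribosomal protein genes, 57 rose and none fell (59 adjusted over the list alone), which became 17 and 4 after rescaling. Rpl3 rose from 198 ± 25.5 to 413 ± 22.2 FPKM, and Rpl10, Rps20 and Rpl38 rose 1.65, 1.63 and 1.63 times. The camera adjusted p was 0.00045 as deposited, 0.72 was the adjusted p with an estimated correlation, and it was 0.11 after rescaling (from 3.1e-09 to 0.72 over the alternatives). Many of these genes have processed copies in the genome, which adds uncertainty to their values.

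Extracellular matrix genes rose together. Of 36 members, 32 rose and none fell (33 adjusted over the list alone), and 31 rose after rescaling. Their median log2 change was 1.94. Postn, which encodes periostin, rose from 29.0 ± 4.34 to 507 ± 117 FPKM (SD, n = 4), Col1a1 from 44.7 ± 6.99 to 196 ± 62.9 FPKM and Col3a1 from 171 ± 15.5 to 389 ± 145 FPKM. Camera gave an adjusted p of 1.9e-08, and the adjusted p was 0.35 with an estimated correlation. Markers of fibroblasts did not move as a group, with 6 of 15 higher and 2 lower (4 and 2 after rescaling, camera adjusted p = 0.95). Mgp and Fbln2 rose 4.33 and 3.96 times, and Clec3b fell from 47.8 ± 4.15 to 10.6 ± 3.26 FPKM. Scara5 fell 3.06 times, with knockout 1 at 6.40 FPKM and the other knockout libraries at 1.27 to 1.57. Of 12 pericyte and smooth muscle markers, 6 rose and 3 fell (4 and 4 after rescaling, camera adjusted p = 0.81). Besides Cnn1, Mcam rose from 29.2 ± 2.49 to 126 ± 9.69 FPKM, while Vtn fell 2.78 times. Tagln rose 4.66 times, with knockout 4 at 333 FPKM and the other knockout libraries at 96.3 to 101. The smooth muscle actin gene Acta2 and the smooth muscle myosin gene Myh11 had log2 changes of -0.07 and 0.36 and did not pass.

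Several stress response genes rose strongly, although camera did not call their lists. Over all 11975 genes tested, 5372 rose and 1964 fell as deposited, and 3225 rose and 3235 fell after rescaling. The counts of members below were not tested against that share. Of 17 p53 target and cell death genes, 9 rose and 2 fell (7 and 2 after rescaling, adjusted p = 0.27). The cell cycle inhibitor Cdkn1a rose from 16.1 ± 0.950 to 205 ± 33.9 FPKM (SD, n = 4), Phlda3 6.31 times, and Zmat3 and Eda2r 2.67 and 2.63 times. Of 21 integrated stress response genes, 13 rose and 2 fell (10 and 3 after rescaling). Atf3 rose 6.78 times, the amino acid transporter Slc7a5 5.96 times and Nupr1 5.07 times (adjusted p = 0.12, and 0.036 after rescaling, from 0.036 to 0.6 over the alternatives with camera). Of 19 endoplasmic reticulum chaperone genes, 13 rose (14 adjusted over the list alone) and 1 fell (9 and 1 after rescaling), the last being Herpud1 with a fall of 2.67 times (adjusted p = 0.088, and 0.014 without knockout 1). Dnajb9, Sdf2l1 and Dnajb11 rose 2.41, 2.14 and 1.88 times. Of 18 antioxidant genes, 10 rose and 3 fell (adjusted p = 0.84), which became 8 and 6 after rescaling, with Gpx3 up from 66.0 ± 8.35 to 613 ± 166 FPKM, Gpx1 up 3.80 times, Srxn1 up 2.49 times and the metallothionein gene Mt2 up 4.72 times. The size of the Mt2 rise depended on knockout 4, without which its log2 change went from 2.24 to 1.59. The rise itself still passed without that library (limma adjusted p = 3.8e-05, against 0.00509 with all libraries). Of 17 hypoxia response genes, 8 rose (9 adjusted over the list alone) and 5 fell (adjusted p = 0.73), which became 4 and 5 after rescaling, Adm and P4ha1 by a rise of 3.13 and 2.06 times and Hk2 by a fall of 1.92 times. Of 13 immediate early genes, 9 rose and none fell (adjusted p = 0.32, and 0.047 without knockout 1), but 4 rose and 1 fell after rescaling. Egr2 rose 3.91 times, Fos 3.47 times, Junb 3.07 times and Egr1 2.59 times. Of 17 circadian clock genes, 4 rose and 6 fell (adjusted p = 0.28), with Hlf and Dbp lower by 2.89 and 2.57 times and Nfil3 higher by 2.39 times.

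Few interferon response genes and cell cycle genes passed as deposited. In the interferon list 1 of 21 members, Ifit2, passed over all genes and none adjusted over the list alone. Its call towards lower values (camera adjusted p = 0.028) ended with an estimated correlation (adjusted p = 0.74), after rescaling (0.099) and without knockout 2, WT 1 or WT 2 (0.094, 0.064 and 0.12), with a range from 0.0022 to 0.74 over the alternatives. After rescaling no member rose and 7 fell. Of 26 cell cycle genes, 3 rose and 1 fell (camera adjusted p = 0.88). Cenpf fell 2.65 times, Tyms rose 1.45 times, and Pcna and Mcm6 rose 2 and 1.68 times. After rescaling 1 rose and 1 fell, and Mcm6 and Tyms did not pass (adjusted p = 0.063 and 0.070).

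Of 20 endothelial markers, 5 rose and 3 fell over all genes and none adjusted over the list alone (camera adjusted p = 0.38). Vwf, Cldn5 and Eng rose 2.51, 1.76 and 1.61 times and Ushbp1 fell 1.52 times, and after rescaling 1 rose and 6 fell. Of 18 macrophage and monocyte markers, 2 rose over all genes, Lgals3 and Ccr2, and none adjusted over the list alone (adjusted p = 0.26). After rescaling 1 rose and 4 fell. Without knockout 4 the change of Lgals3 went from 2.17 to 1.58. None of 6 lymphocyte markers and none of 8 erythroid markers passed (adjusted p = 0.26 and 0.57). The lymphocyte genes Cd52 and Lck had log2 changes of 0.42 and -0.75, and the globin genes Hba-a1 and Hbb-b2 of -0.03 and -0.30. In the adipocyte list 1 of 7 rose, Cidea (adjusted p = 0.81), and among epicardial and mesothelial markers 2 of 9, Aldh1a2 and Tbx18 (adjusted p = 0.75), of which Tbx18 did not pass after rescaling. Without knockout 1 the change of Aldh1a2 went from 1.97 to 2.62. The medians of the adipocyte, epicardial and lymphocyte lists were 1.20, 0.92 and -0.66 on the log2 scale, with Ucp1, Cfd and Msln highest in knockout 4 (102, 84.2 and 20 FPKM) and Lck at 11.7 FPKM in WT 3 against 0.204 to 0.48 in the other WT libraries. Lists with fewer than 5 members past the expression minimum were not tested. Of these, 2 of 3 neutrophil markers rose, Lcn2 and S100a8 (Lcn2 alone after rescaling), and 1 of 4 Schwann cell and neuron markers fell, Dbh. Of 4 skeletal muscle markers, Tnnt3, Myl1 and Mylpf rose and Tnni2 fell. None of 4 lung and thymus markers passed, and none of 4 sex-linked genes. Ddx3y on the Y chromosome stood at 21.4 to 31.5 FPKM in all 8 libraries, with log2 changes of 0.23 for Ddx3y and 0.21 for Eif2s3y as deposited and of -0.03 and -0.06 after rescaling. Xist was at 3.22 FPKM in knockout 3, 0.606 in knockout 2 and at most 0.0643 in the other libraries.

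Atrial markers moved in both directions. Of 11 members, 6 rose and 4 fell (5 and 4 after rescaling, camera adjusted p = 0.77). Nppa, Dkk3 and Gja5 rose together with Myl7, Myl4 and Sln, and the channel and receptor genes Kcnj3, Kcnj5, Chrm2 and Kcna5 fell by 3.38, 2.01, 1.03 and 0.34 on the log2 scale. Myl7, the atrial myosin light chain, stood at 61.6, 42.6, 2.50 and 726 FPKM in the knockout libraries and at 0 to 0.680 in WT. Without knockout 4 its log2 change went from 5.22 to 3.95, and without knockout 3 to 6.51. That of Myl4 went from 3.98 to 2.94 and 4.70, and that of Sln from 3.93 to 2.71 and 5.06. Knockout 1 also held low levels of other genes particular to knockout 4, as given below. If these are material or reads of knockout 4, leaving out knockout 4 alone does not remove all of them. Sln was listed at 0 in all 4 WT libraries and at 18.6, 9.11, 0.429 and 188 FPKM in the knockout libraries. It did not pass with array weights (adjusted p = 0.073, from 0.0013 to 0.073 over the alternatives). Nppa showed no such spread, with 7300, 7830, 5020 and 5760 FPKM in the knockout libraries.

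Some libraries also held transcripts of tissues other than heart. Knockout 4 had 102 FPKM of the brown fat gene Ucp1, 111 FPKM of the airway gene Scgb1a1 and 66.0 FPKM of Bmp10, an atrial gene. Knockout 1 had 8.82, 11.1 and 6.21 FPKM of these, and the remaining knockout libraries at most 0.504. WT 3 had 10.1, 11.3 and 11.8 FPKM of the thymocyte genes Rag1, Dntt and Cd8b1, against at most 0.282 in each other library. Leaving out knockout 4 and WT 3, a choice made after seeing the data, left 4906 higher and 1835 lower genes and 17 lists called. Leaving out knockout 1 as well left 4770 and 1850 genes and 21 lists.

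**Figure D3:**
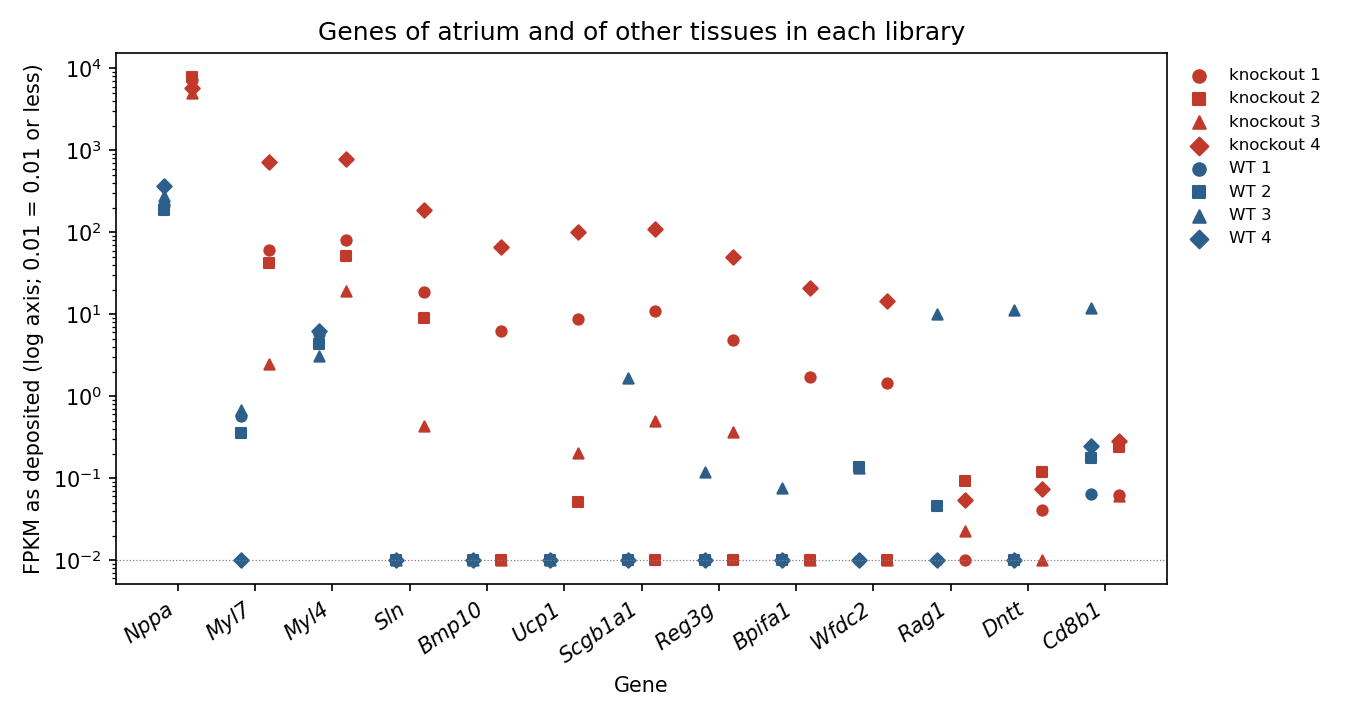
FPKM on a log axis for 13 genes of atrium, fat, airway and thymus in each library, blue for WT and red for knockout, with 1 symbol per library and values of 0.01 or less drawn at 0.01. Knockout 4 is highest for Myl7 (726 FPKM), Ucp1 (102) and Scgb1a1 (111), WT 3 is highest for Rag1 (10.1), and Nppa lies between 5020 and 7830 FPKM in all 4 knockout libraries.

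**Figure D4:**
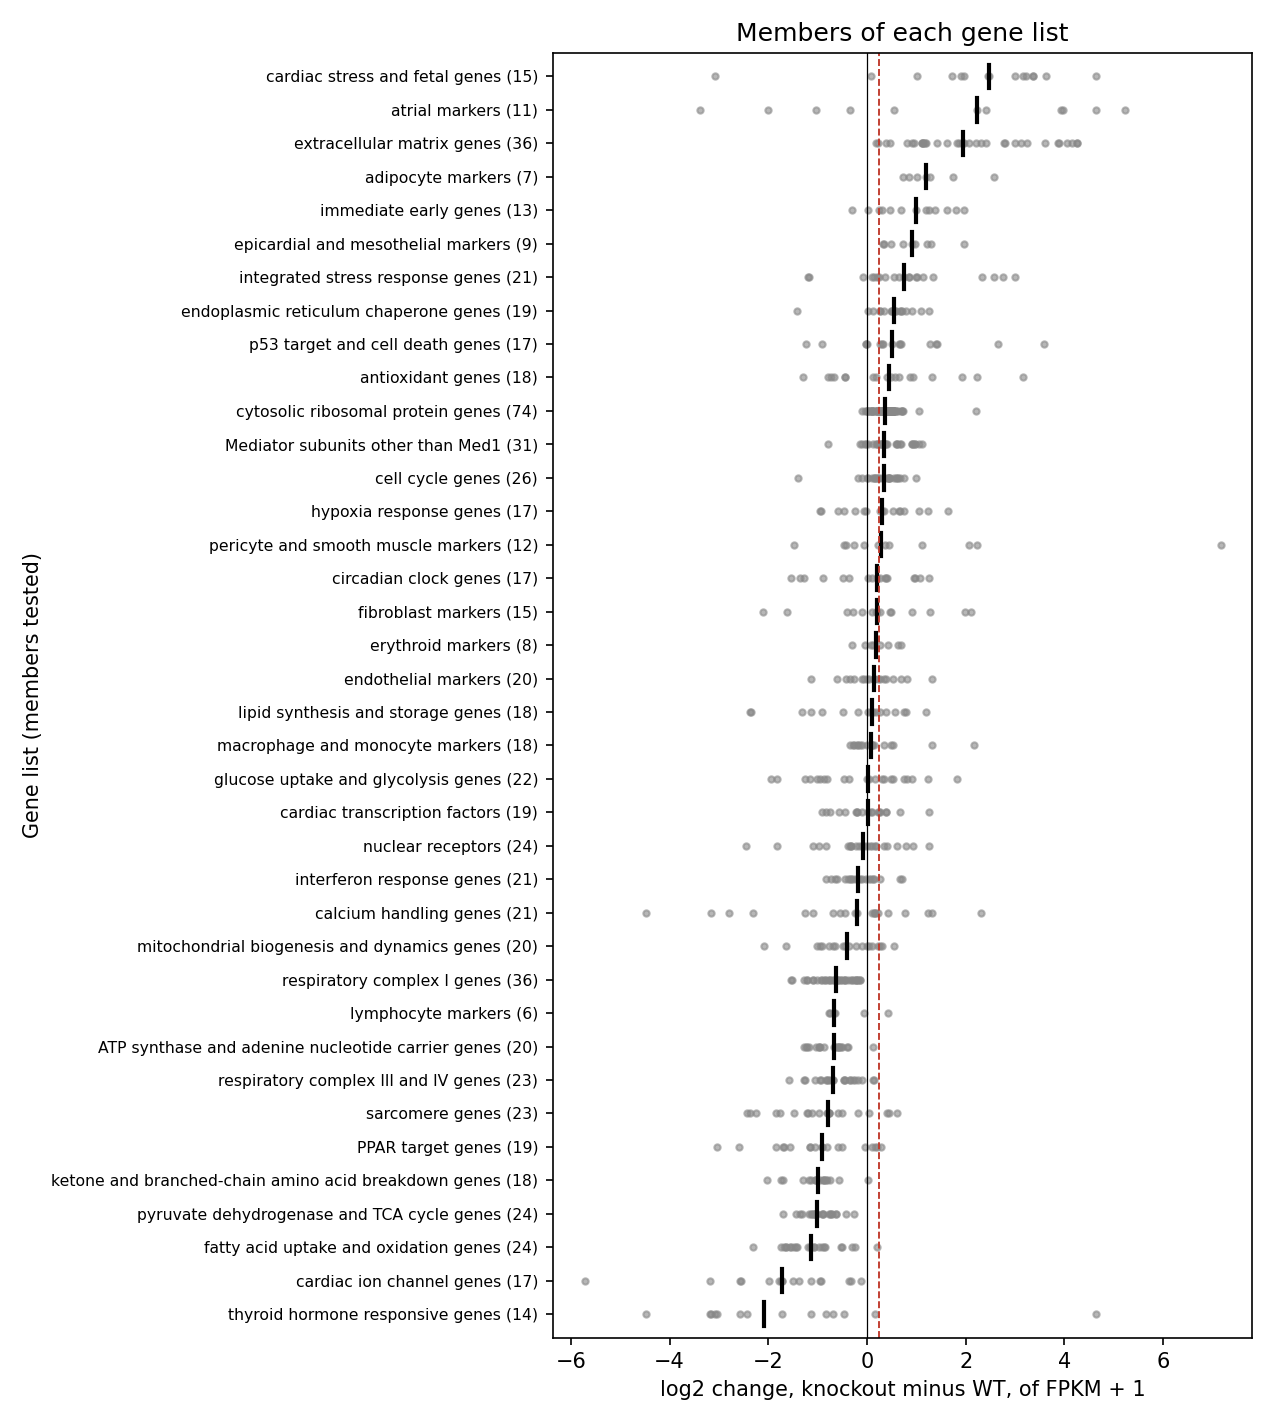
Log2 change (knockout minus WT, of FPKM + 1) of each member tested, 1 grey point per gene, in the lists with at least 5 members tested, whose number is in parentheses. Black bars are list medians, from -2.08 for thyroid hormone responsive genes to 2.48 for cardiac stress and fetal genes, and the dashed line is the median of all genes (0.25).

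Of 44 lists, 38 were large enough to test, and camera with its preset correlation called 17, with 3 higher and 14 lower. With the correlation estimated per list 1 was called, and the rotation test fry, which does not compare a list with other genes, called 24. Camera called as many lists in 15 of the 35 ways to split the 8 libraries into 4 and 4, the real one included. Of the 14 others, 12 keep 3 libraries of a group together and so carry part of the contrast. These splits thus cannot decide whether the number of lists exceeds chance, which is not excluded. The counts of members were not tested against those over all genes, where 5372 of 11975 rose and 1964 fell. Median, mean and camera direction differed in sign for cardiac transcription factors, lipid synthesis, glycolysis, hypoxia, cell cycle, fibroblast, endothelial, macrophage, erythroid, atrial and circadian lists, none of which was called.

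The authors' deposited table listed 5745 significant genes, with 2892 higher and 2853 lower in the knockout. Of 5473 that could be matched to the genes tested here, 4531 passed in limma, each in the same direction, and 5095 passed after rescaling. A further 2770 matched genes passed in limma as deposited and were not significant in the authors' deposited table. Med1 had 18.9 FPKM in WT and 8.76 FPKM in the knockout in the authors' deposited table, a log2 change of -1.11. Cnn1 and Nppa had log2 changes of 7.73 and 4.38 there, and Pln one of -4.73.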

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

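The tests on contractile genes, on Nppa and on knockout 1 sharing transcripts with knockout 4 were chosen after the results were seen, and those on the splits before. The test on atrial markers names knockout 4 as highest and knockout 3 as lowest in Myl7, so it was framed with those values known. The test on the median of all genes likewise starts from a median already known to be higher. The real split of the 8 libraries called 7336 genes, and among its 35 splits into 4 and 4 it was the 1 that called as many. The highest of the other splits called 1 gene. Every other split puts knockout and WT libraries on both sides, so that their difference adds to the spread within a side. Few calls there follow from this, so the splits do not measure how many genes chance would call. For the 17 gene lists that camera called, 15 of the 35 splits called as many, the real one included and the highest other at 26, so chance cannot be excluded for that count. Of the 14 others, 12 keep 3 libraries of a group together and carry part of the contrast between the groups.

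In 23 of 334 groups of 4 libraries 1 library stood far from the other 3, where chance gives about 5 percent. In FPKM, with the range of the other 3 in parentheses, knockout 4 stood apart for Ces1d at 7.77 (0.747 to 0.904), Tbx20 at 48.8 (53.4 to 54.2), Cox6a2 at 862 (1130 to 1190) and Tagln at 333 (96.3 to 101). Knockout 3 did for Ryr2 at 14 (22.2 to 22.8) and Gpam at 15.8 (18.3 to 18.9). Knockout 1 did for Idh3b at 148 (221 to 236), Scara5 at 6.40 (1.27 to 1.57), Cldn5 at 38.5 (25.4 to 26.4), Tnnt3 at 11.7 (3.42 to 4.29) and Junb at 9.72 (19.1 to 21.7). WT 2 did for Nr1h3 at 5.4 (3.78 to 3.99), Lpin1 at 29.2 (36.8 to 38.3), Ushbp1 at 29.6 (19.7 to 21.1), Mcam at 25.5 (30.1 to 30.7) and Rpl3 at 237 (185 to 186). WT 3 did for Uqcrc1 at 772 (700 to 711), Lck at 11.7 (0.204 to 0.48), Cd8b1 at 11.8 (0.0638 to 0.249) and Scgb1a1 at 1.68, listed at 0 in the others. WT 4 did for Med15 at 6.96 (8.43 to 8.57), Gpx1 at 84.4 (72.2 to 73.7) and S100a8 at 4.62 (3.24 to 3.38).

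Contractile genes were lower in the knockout. A lower share of cardiomyocyte RNA as the whole cause would move them by 1 factor, but the SD of their log2 changes was 0.86 against 0.28 for 2 times their median standard error, which argues against it. The 79 markers of 6 other cell types lay at -0.15 relative to all genes (95% bootstrap interval -0.28 to -0.03, 10000 resamples). Markers were resampled as if independent and libraries were not, so the interval leaves out the spread between libraries. Called members went both ways and a common rise would also move the median of all genes. The markers thus leave a gain of other cell types open. Lower levels of these transcripts within cardiomyocytes may explain the fall and stay a hypothesis, since a smaller share as a part of the cause was not excluded.

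Myl7, Myl4 and Sln were unequal between the knockout libraries. The ratio of knockout 4 to knockout 3 over 8 other atrial markers lay at percentile 100 of 10000 matched random lists (median log2 ratio 0.61, against 0.16 for the 95th percentile). Kcna5 and Gja5 went the other way (-0.39 and -0.13), while the others were higher in knockout 4, Bmp10 most (6.07). Atrial tissue is thus a candidate source of the unequal levels. It is argued against as the source of the higher Nppa, since knockout 3, with the least Myl7, had 87.1% of the Nppa of knockout 4. For 11 genes that the 6 other libraries hold at 2 percent or less of their level in knockout 4, knockout 1 held a median of 9.49% of the level of knockout 4 (quartiles 8.73 and 9.93, range 4.8 to 12.3), so material or reads of knockout 4 in knockout 1 is a candidate explanation. Added atrial tissue would not lower Kcnj3 (0.41 to 1.91 FPKM in the knockout libraries, 14.4 to 22.2 in WT), and whether Myl7, Myl4 and Sln also rose in the muscle of the ventricle stays open.

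The median of all genes was higher in the knockout by 0.25. The 200 genes most abundant in WT held 35.5 to 36.7% of the FPKM total in the knockout libraries and 51.8 to 54.2% in WT. Dividing by the total without these genes brought the median to -0.05, against 0.32 after division by the plain total, but this division itself centres the remaining genes. Whether abundant cardiac transcripts fell or the others rose cannot be told apart by it. A change in the total amount of RNA per cell was not tested, as no reference of known amount was named in the labels.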

How the results depend on the processing

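The settings with 3 against 3 and with 2 against 3 libraries, and the comparison of the authors' FPKM with the libraries, were chosen after the data were seen. Med1 passed under all 19 alternatives (log2 change -1 to -0.68, adjusted p 8.9e-05 to 0.0045). Genes called ranged from 5705 (at least 5 FPKM) to 7873 (array weights). Leaving out 1 library gave 6710 to 7208 genes and 16 to 19 lists. Of the named genes' values, 3033 kept call and direction, 57 lost the call, 6 gained it and 11 reversed. Rescaling gave 3225 higher and 3235 lower genes and quantile normalization 3437 and 3066, which remove the common shift by construction, and the authors' test 2892 higher. Over 11170 genes compared, their pooled FPKM were a median of 1.29 times the mean of the libraries in WT (5th to 95th percentile 1.27 to 1.29) and 1.06 times in the knockout (1.04 to 1.06). Their values thus carry a scaling between the groups of 1.22 times, the same as that of the size factors, which takes the median log2 change of these genes from 0.28 to 0.

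Reversed changes did not pass on either side. They were -0.06 for Eif2s3y and -0.03 for Ddx3y after rescaling, -0.06 and -0.02 after quantile normalization, and 0.49 for Hba-a1 after the latter. Leaving out 1 library gave -0.61 to 0.43 for Hba-a1 and -0.74 to 0.17 for Hbb-b2. Rescaling ended 9 calls of named genes (Eng, S100a8, Tbx18, Mcm6, Tyms, Cldn5, Ccr2, Egr1 and Ifit2) and quantile normalization 8 (these without Tyms and Egr1, and Slc25a4). Cldn5, Ccr2, Egr1 and Ifit2 also lost their call in several settings that leave out 1 library, and Eng without WT 4 (0.62, adjusted p 0.053). Cd52 gained it without knockout 3 (0.56, 0.039), Scgb1a1 without knockout 2 (3.31, 0.044), and Ddx3y and Eif2s3y without knockout 1 (0.31 and 0.37).

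Of 17 lists called, 15 were called under all 19 alternatives to data or model and by fry. List values are the mean log2 change of a list minus that of the other genes. With an estimated correlation 1 list was called, thyroid. Calls were lost, at unchanged values, for stress and fetal (1.99), sarcomere (-1.13), calcium (-0.8), ion channel (-1.96), nuclear receptor (-0.39), fatty acid (-1.34), PPAR (-1.2), TCA (-1.18), complex I (-0.89), complexes III and IV (-0.83), ATP synthase (-0.96), mitochondrial biogenesis (-0.65), ketone and amino acid (-1.25), interferon (-0.36), matrix (1.89) and ribosomal lists (0.18). Both camera runs share data and model and differ in how the correlation is set. For these lists the estimate ran from 0.032 (nuclear receptor) to 0.68 (interferon), against the preset 0.01, so the small p-values rest on that preset. Fry, which tests a list by itself, lost interferon (-0.36) and gained Mediator (0.2), glycolysis (-0.36), integrated stress (0.62), chaperone (0.26), antioxidant (0.26), p53 (0.47), mural (0.7) and immediate early lists (0.69).

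For the other changes of a list the cause was not tested. The interferon call was lost at 5 FPKM (-0.42), rescaled (-0.35), quantile normalized (-0.36), with array weights (-0.3) and without knockout 2, WT 1 or WT 2 (-0.5 to -0.19 over all libraries left out), and the ribosomal call rescaled (0.14). Gained were Mediator (0.23), chaperone (0.32) and lymphocyte (-0.5) without an expression minimum, lipid synthesis (-0.55) at 5 FPKM, integrated stress rescaled (0.64) and quantile normalized (0.63), and Mediator (0.22), lipid synthesis (-0.55) and glycolysis (-0.38) with array weights. Leaving out 1 library gained chaperone (0.21 to 0.35) and immediate early (0.44 to 0.94) without knockout 1, glycolysis (-0.38 to -0.33) without knockout 2 or WT 2 and lipid synthesis (-0.56 to -0.37) without knockout 4 or WT 4. With 2 against 3 libraries chaperone (0.32), macrophage (-0.36) and immediate early (1.1) were gained, and cell cycle (0.53) was called towards higher values. With the replicate number as a block 6956 genes and 18 lists were called, the Mediator list (0.2) among them. The labels do not say whether the numbers pair the libraries. Of 4 pairs with the same number, 1 correlated over 0.1 in its deviations from the group means, which does not decide it.

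Sex was not fitted, as the labels give none and all 8 libraries held Ddx3y at 21.4 to 31.5 FPKM. Xist, at 3.22 FPKM in knockout 3 and 0.606 in knockout 2, leaves some female material in these libraries open. Relative depth ran from 0.97 to 1.1, and what the absolute depth limits is unknown.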

Other observations

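The gene families and isoform pairs of this part were chosen after the values were seen. In 18 of 22 pairs of a muscle or heart isoform with a broadly expressed or other partner, the ratio of muscle to partner was lower in all 4 knockout libraries than in all 4 WT libraries, and in none higher. The log2 ratio changed by -5.35 for Rpl3l to Rpl3, -3.77 for Pfkm to Pfkp, -3.21 for Tnni3 to Tnni1, -3.2 for Ckm to Ckb, -3.07 for Slc2a4 to Slc2a1 and -2.1 for Eef1a2 to Eef1a1. Among all genes tested, 57.1% had libraries of the groups apart, but that share is of single genes, in either direction and as deposited. No share over other pairs of genes was computed, so the 18 of 22 pairs have no like background. A scaling factor cancels in a ratio within a library, apart from the 1 FPKM added to each value. The partner itself rose for Rpl3, Pfkp, Slc2a1, Ckb (38.1 to 129 FPKM) and Eef1a1 (739 to 2180 FPKM), while Tnni1, at 0.338 FPKM in WT and 1.64 in the knockout, was below the expression minimum and not tested. The 4 other pairs were Cox8b to Cox8a (-0.6), Pygm to Pygb (0.5), Phka1 to Phka2 (-0.38) and Myh6 to Myh7 (0.64).

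Families were taken by the start or the end of the gene symbol, with camera adjusted p and then the adjusted p with an estimated correlation. As the families were picked from these same data and adjusted over themselves alone, these p-values describe them and are no independent test. Genes with Psm symbols, which are proteasome subunits, activators, assembly factors and Psmc3ip, rose in 35 and fell in 5 of 46 (25 and 8 after rescaling, 0.0088 and 0.48), genes with Eif symbols, which besides initiation factors include kinases, repressors and Argonaute genes, in 41 and 5 of 57 (21 and 8, 0.0067 and 0.3), cytosolic aminoacyl-tRNA synthetases in 12 and 1 of 17 (11 and 2, 0.0088 and 0.3) and chaperonin subunits in 7 and 0 of 7 (5 and 0, 0.0098 and 0.35). Mitochondrial ribosomal proteins rose in 12 and fell in 41 of 76 (6 and 57 after rescaling, 1.8e-09 and 0.3). Histone genes rose in 34 and fell in 1 of 42 (28 and 1, 0.00028 and 0.38), and reads of their near-identical copies are uncertain, as poly(A) selection of histone RNA also is. Tubulins rose in 7 and fell in 0 of 13 (7 and 2, 0.33 and 0.75), and genes with Itga or Itgb symbols, 16 integrins and 4 others, in 10 and 2 of 20 (7 and 3, 0.15 and 0.3).

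Cfd, a fat gene, stood at 84.2 FPKM in knockout 4, 8.25 in knockout 1 and 10.4 in WT 3, and Msln, a mesothelial gene, at 20, 2.03 and 3.09.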
